A study of Homo sapiens with 5 samples.

How the data were processed

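RNA of SH-SY5Y cells was profiled in 5 libraries, 1 in each of 5 groups, named siControl, siSTAU1, siUPF1, Nondifferentiation and Differentiation after the sample titles. Per the labels' protocols, RNA was extracted with Trizol and 500 ng of total RNA entered a Lexogen QuantSeq kit, which sequences the 3' ends of polyadenylated RNA, so a gene's value does not scale with its length. The growth media labels list 10% serum and 1% antibiotics for all groups and 50 uM retinoic acid for Nondifferentiation and Differentiation. Groups were taken from the titles alone.

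The deposited values were log2 expression values, 1 per gene symbol and library, for 26364 symbols. Bowtie2, edgeR and genome build hg19 are named in the submitters' processing notes, without role or version. The counting tool, the gene annotation and strand use are not given in the sources used here. The values themselves show that the deposited log2 values had been brought to a common distribution over the 5 libraries: the highest value was 18.01 in each, and the upper quartile lay between 8.63 and 8.64. In linear form 100% of values above 0 were multiples of 1/5 within a tolerance of 0.001, as means over 5 libraries of whole read counts are. This pattern is that of quantile normalization, which is an inference from the values. Such scaling removes differences between libraries in total RNA and in the overall distribution of values.

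Between 9583 and 9932 genes per library were at exactly 0, apparently genes without reads. In Differentiation 478 genes lay below 0, at -1.32, apparently genes with 1 read, and its 0 block may also hold genes with about 2 reads. Genes at 0 are therefore called listed at 0, and no fold of a single gene is printed or drawn against such a value or against one from about 3 reads or fewer, although such folds enter the list medians. Depth was estimated from the steps between the lowest values. A read was worth 1.26 linear units in siControl, 1.24 in siSTAU1, 1.09 in siUPF1, 1.05 in Nondifferentiation and 0.604 in Differentiation, for estimated totals of about 15400000, 15800000, 17900000, 18600000 and 32300000 reads. At the floor for measured genes the counting SE of a log2 fold was estimated at 0.151 for siSTAU1, 0.146 for siUPF1 and 0.126 for Differentiation. These figures cover counting error only, and the spread between cultures is unknown.

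Log2 folds were differences of the deposited values: siSTAU1 and siUPF1 against siControl, and Differentiation against Nondifferentiation. siControl was also set against Nondifferentiation. A gene was measured when the larger of its 2 values was at or above the median of all nonzero values of those libraries, a log2 value of 7.84, 7.84, 7.76 and 7.81 in these 4 comparisons. It was counted as higher or lower at a threshold of 2-fold. No test was run, because each group had 1 library. The rule for naming genes was fixed before the data were examined. It took STAU1, UPF1, the 10 highest and 10 lowest log2 folds of each comparison and up to 2 highest and 2 lowest members of each gene list. For the overlap it took the 10 genes with the largest smallest fold. Apart from STAU1 and UPF1, the genes it picked are thus extremes of these data and were not predicted. XIST and Y-linked genes were left out. Some of the genes so chosen are not reported here. RARB, DSCAM, ZNF790, the gene names behind the pairwise overlaps and the genes of other cell types outside the preset lists were named after their values were seen.

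Gene lists for decay factors, Staufen- and nonsense-mediated decay targets, retinoic acid, HOX, neuronal, synaptic, noradrenergic, cell cycle, stress, interferon, cholesterol, p53, hypoxia, Notch, histone, mitochondrial and ribosomal genes were also fixed before the data were examined. So were markers of mesenchymal, glial, epithelial and blood cells. A list's median log2 fold was placed among those of 10000 random lists of the same size drawn within 20 bins of mean expression, as a description of these libraries. Percentiles were given for lists with at least 3 measured members. Lists of imprinted, autophagy, luminal breast and hepatocyte genes were written later.

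Overlaps were set beside the product of the lists' shares, which takes no account of changes that bring a gene over the floor. Counting error was simulated in 100 draws of unchanged libraries at the estimated depths that used the same siControl. Correlations and covariances across genes used genes measured in both comparisons, with 1000 bootstrap draws of genes. GC content and length of the longest GENCODE 29 transcript were matched by symbol for 95.9% of measured genes in each of the 3 comparisons. The reference annotation was of another build than hg19, so no positions are printed. Calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data with 100 genes at 3-fold and 100 at 1.5-fold. At the 2-fold threshold 97% of 3-fold genes were recovered for siSTAU1 among 8128 genes, 94% for siUPF1 among 8128 and 98% for Differentiation among 8338, with 0% of 1.5-fold genes and 0 unchanged genes called. The 0% follows from the threshold. The 0 unchanged genes are no false-call rate for these libraries. siControl against Nondifferentiation, without knockdown or differentiation, had 68 calls, although that pair also differed in transfection and in the labelled medium.

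The alternatives fixed before the data were examined were subtraction of the median fold, repeated quantile normalization, no filter, an upper quartile filter, thresholds of 1.5- and 3-fold and Nondifferentiation as the reference of the knockdowns. The design foresaw count methods in case of counts, and these were not used. A smaller pseudocount, planned for linear values, was not used on log2 values. A pseudocount of 10 linear units, siControl as the reference of Differentiation, Nondifferentiation as the reference for gene lists of the knockdowns and the removal of GC and length trends were added later.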

Results

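Gene expression was measured in SH-SY5Y, a human neuroblastoma cell line that can be driven towards a neuron-like state, in 5 libraries made by 3' end sequencing. The libraries stood for 5 groups of 1 library each: cells given a control siRNA (siControl), an siRNA against STAU1 (siSTAU1) or an siRNA against UPF1 (siUPF1), and cells labelled Nondifferentiation and Differentiation. STAU1 is a protein that binds double-stranded RNA, and UPF1 is the helicase at the centre of nonsense-mediated decay and of Staufen-mediated decay, in which STAU1 recruits UPF1 to mRNAs. The design asks which transcripts were higher both after depletion of either factor and with differentiation. Each library gave a log2 value for 26364 gene symbols. Depth was estimated from the spacing of the lowest values at about 15400000 reads for siControl, 15800000 for siSTAU1, 17900000 for siUPF1, 18600000 for Nondifferentiation and 32300000 for Differentiation. With 1 library per group no difference has a replicate check, so genes are described by the size of the difference between 2 libraries, and no p-value is given. A gene is counted as higher or lower when its value differed by at least 2-fold.

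The targeted mRNAs were lower in the libraries labelled for their siRNAs and nearly level in the differentiation pair. STAU1 stood at 12.87 in siControl and 11.34 in siSTAU1, a log2 fold of -1.52, which is 2.88-fold lower. It stood at 12.89 in siUPF1. UPF1 stood at 10.74 in siControl, 10.64 in siSTAU1 and 9.20 in siUPF1, where the log2 fold of -1.53 is 2.90-fold lower. In Differentiation against Nondifferentiation the log2 fold was -0.01 for STAU1, from 12.86 in both libraries, and 0.07 for UPF1, from 10.62 to 10.69. The design text describes reduced levels of both factors in differentiation, without saying whether of mRNA or protein. A lower mRNA was not seen for either in these libraries.

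**Figure D1:**
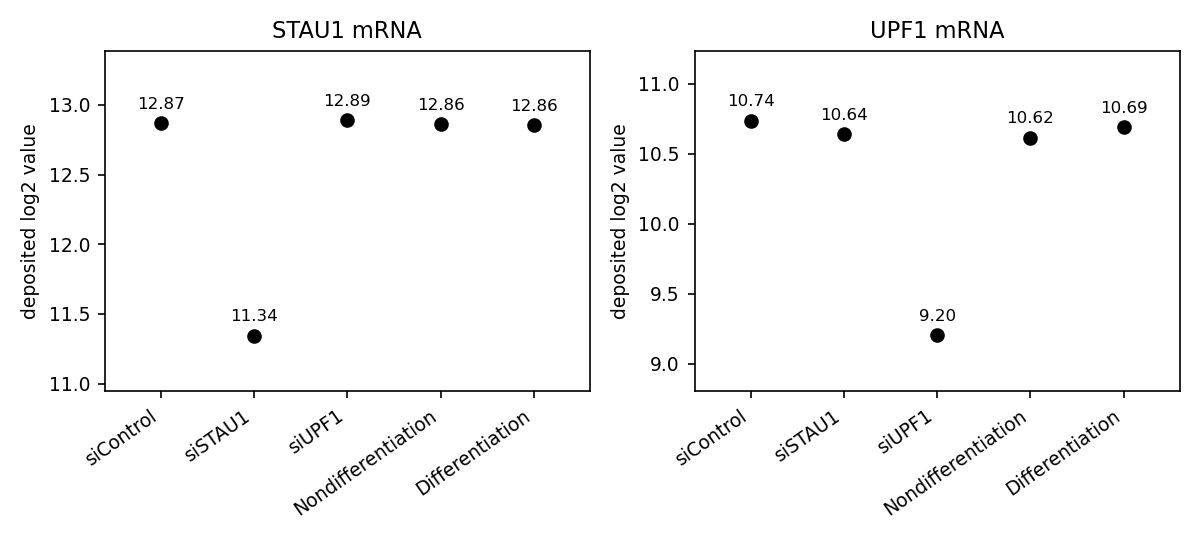
Deposited log2 value of STAU1 mRNA (left) and UPF1 mRNA (right) in each of the 5 libraries, 1 point per library, on axes that do not start at 0. STAU1 was lowest in siSTAU1 at 11.34 and UPF1 was lowest in siUPF1 at 9.20, while Nondifferentiation and Differentiation lay close together for both.

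Few genes differed between siSTAU1 and siControl. Of 8453 measured genes, 8 were higher and 9 were lower, STAU1 among them. TUBA1C, an alpha-tubulin, had a log2 fold of 1.43. DCX, a microtubule-binding protein of migrating neurons, had 1.11, and PRICKLE1, a planar cell polarity protein, had 1.03. RTEL1, a helicase that protects telomeres, had 1.18, and the growth factor NRG1 had 1.11. SNORA12, a small nucleolar RNA, had 1.08, and IGFBP3, a secreted binding protein of insulin-like growth factors, had 1.07. The kit reads polyadenylated RNA, and whether reads counted under SNORA12 came from the small RNA itself was not examined. ALAS1, the first enzyme of haem synthesis, and TSACC followed just under 2-fold, at 0.99 and 0.95. TAGLN, an actin-binding protein, had the lowest log2 fold, -1.63, ahead of the interleukin receptor subunit IL17RE at -1.62 and STAU1. The kinase PAK4 had -1.32, TADA2A, an adaptor of histone acetyltransferase complexes, had -1.25, and SLC16A4, a member of the monocarboxylate transporter family, had -1.20. QARS, the glutaminyl-tRNA synthetase, had -1.14, FAM114A1 had -1.06, and the microtubule-associated MAP1S had -0.95. PDE4DIP, a centrosomal and Golgi protein, was just 2-fold lower, at 8.20 against 9.21. Against Nondifferentiation 24 genes were higher and 54 were lower, but only 3 of the 8 and 4 of the 9 calls held: DSCAM-AS1, TUBA1C and IGFBP3, and TAGLN, STAU1, PAK4 and FAM114A1. Holding is no independent check, because the gap between siControl and Nondifferentiation enters it. IGFBP3 had 2.30 in siControl itself against Nondifferentiation, and TUBA1C stood at 7.56 in siControl and 6.90 in Nondifferentiation. With that reference NRG1 had 0.06, SNORA12 0.02, PDE4DIP -0.19 and TADA2A -0.47, while RTEL1 had 0.99. IL17RE had -1.12 and was lost only because both values lay below the floor.

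The highest log2 fold in siSTAU1, 5.61, belonged to DSCAM-AS1, a long noncoding RNA best known from oestrogen receptor-positive breast cancer cells. It stood at 8.09 in siSTAU1, 2.49 in siControl, 5.29 in siUPF1 and 3.54 in Differentiation, and was listed at 0 in Nondifferentiation. The siControl value came from a few reads, so the size of this fold is imprecise. DSCAM, the gene it overlaps on the other strand, stood at 5.11 in siSTAU1 and was listed at 0 in siControl, and strand use in counting is not given in the sources used here. Epithelial markers stood out in siSTAU1 and, at lower values, some did in siUPF1 and Differentiation. KRT18 stood at 7.56 in siSTAU1, 4.74 in siUPF1 and 2.49 in siControl, and KRT8 at 7.53, 4.23 and 2.49. ESR1, the oestrogen receptor, stood at 5.71 in siSTAU1 and 4.74 in siUPF1 while listed at 0 in siControl. In Differentiation KRT8 stood at 4.58, KRT18 at 3.54 and ESR1 at 3.41. The preset list of 10 epithelial markers had a median value of 4.73 in siSTAU1, 2.71 in Differentiation, 0.26 in siUPF1 and 1.04 in siControl, although no member reached the measured floor.

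Most preset gene groups lay near 0 in siSTAU1. The synapse and secretory granule list, with 8 measured members, had a median log2 fold of -0.23, at the 0.47 percentile of 10000 random lists matched on expression. Its lowest members were the granule protein VGF at -0.35 and the vesicle calcium sensor SYT1 at -0.35, and its highest was the neuropeptide NPY at 0.47. Without the filter on low values its median was -0.03. The decay factor list, with 21 measured members including STAU1 itself, had a median of -0.10 at the 2.19 percentile, and at the 3.08 percentile after trends with GC content and length were removed, with UPF2 at -0.66 and STAU2 at 0.31. Of the 6 measured mRNAs reported as Staufen-mediated decay targets, 0 were 2-fold different, and their median was 0.11 at the 85.2 percentile. Against Nondifferentiation the median was -0.17, with 5 of 6 negative, where siControl itself had -0.28, also with 5 of 6 negative. Against siControl DPF2 had 0.31, GAP43, a growth cone protein, had 0.23, and CYR61 had -0.18. The 19 measured nonsense-mediated decay targets had a median of -0.09. The medians of the other preset lists with at least 5 measured members lay in the middle 95% of random lists. With Nondifferentiation as the reference the decay factor list had -0.04, inside that range. The synapse list had -0.39, where siControl itself had -0.41, and cholesterol synthesis had -0.37, where siControl had -0.36. The retinoic acid response had -0.55 and mesenchymal markers -0.40, both below all 10000 random lists, where siControl had -0.30 and -0.24. Also outside the middle 95% were mitotic genes at 0.34, ribosomal genes at 0.10 and immediate early genes at -0.35. So were hypoxia and glycolysis at -0.25, the p53 response at -0.22, the stress list at -0.19 and Notch genes at -0.16. The siControl medians of these lists lay on the same sides. Against siControl the immediate early and p53 medians were 0.15 and 0.11.

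More genes were higher than lower in siUPF1 against siControl. Of 8474 measured genes, 34 were higher and 12 were lower, UPF1 among the latter. Against Nondifferentiation the balance turned round, with 46 higher and 71 lower, and 15 of the 34 and 5 of the 12 calls held. siControl itself had 19 higher and 49 lower with that reference. ALB, which encodes serum albumin, had the highest log2 fold at 2.66, from 6.36 in siControl to 9.02. ZNF790-AS1 followed at 2.04, while ZNF790, the coding gene it lies opposite, had 0.05. KIAA0319, a membrane protein studied in dyslexia, had 1.54, TAGLN 1.52 and ASL, an enzyme of the urea cycle, 1.45. PTRF, a coat protein of caveolae, had 1.41, IGFBP3 1.41, DMD, which encodes dystrophin, 1.39, COX19, an assembly factor of cytochrome oxidase, 1.37 and the transcription factor PAX6 1.36. The lowest after UPF1 were the kinase CDC42BPB at -1.43, the small Cajal body RNA SCARNA22 at -1.33 and PPFIA2, a presynaptic scaffold protein, at -1.26. Whether reads counted under SCARNA22 came from the small RNA itself was not examined. The uncharacterised LOC642366 had -1.24, the mucin MUC1 -1.19, GSTT2 -1.16, the transcription factor TRERF1 -1.07, LOC90768 -1.07 and TADA2A -1.05. GSTT2 has a near-identical copy, so its value is uncertain. Among these the calls that held were ALB, ZNF790-AS1, TAGLN, IGFBP3, DMD, COX19, UPF1, SCARNA22, LOC642366 and MUC1, while PTRF had 0.23 and CDC42BPB -0.57 against Nondifferentiation. For IGFBP3 this is no check of the knockdown, since siControl itself had 2.30 with that reference. TAGLN went opposite ways in the 2 knockdown libraries with either reference. TADA2A was lower in both against siControl, where it stood at 8.32, but had -0.47 in siSTAU1 and -0.27 in siUPF1 against Nondifferentiation.

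The 19 measured nonsense-mediated decay targets had a median log2 fold of 0.36 in siUPF1, above all 10000 random lists. ATF3, a stress-induced transcription factor, had 1.19 and UPP1, a uridine phosphorylase, had 1.07, and these 2 were counted as higher. The cell cycle inhibitor CDKN1A had 0.94 and the stress regulator ATF4 had 0.72, while SNHG12 had -0.37 and UPF2 -0.18. With Nondifferentiation in place of siControl, 20 members were measured and the median was 0.29, again above all 10000 random lists. Single members did not all keep their side. ATF3 stood at 9.22 in siUPF1 and 8.53 in Nondifferentiation, UPP1 at 7.94 and 8.29 and CDKN1A at 10.77 and 11.66, so neither call held there and UPP1 and CDKN1A turned. The 6 Staufen-mediated decay targets had a median of 0.28 at the 98.2 percentile, with 0 members past 2-fold, JUN at 0.43 and DPF2 at 0.36. With Nondifferentiation as the reference that median was -0.04, where siControl itself had -0.28. The decay factor list had 0.03, with SMG9 at 0.52, and 0.23 against Nondifferentiation.

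Other groups also stood apart in siUPF1. The siUPF1 folds went with GC content, with a Pearson r of 0.27 across genes, and with length, with a Spearman r of -0.12, against -0.01 and -0.03 in siSTAU1, so the lists were also placed after these trends were removed. The nonsense-mediated decay targets then had 0.39, above all 10000 random lists, and the p53, immediate early, mesenchymal, noradrenergic and ribosomal medians stayed outside the middle 95%. The Staufen-mediated decay targets, at the 97.2 percentile, and the hypoxia and glycolysis list, at 4.15, lay inside it, and S phase genes left it, at -0.13 and the 1.47 percentile. The p53 response list had a median of 0.26 at the 99.96 percentile over 15 members, led by FDXR, a mitochondrial reductase, at 1.22 and at -0.01 against Nondifferentiation. The immediate early list had 0.35 at the 99.7 percentile over 7 members, led by ATF3 and by EGR1 at 0.47. Both medians were negative with Nondifferentiation as the reference, at -0.21 and -0.07, where siControl itself had -0.38 and -0.50. The mesenchymal neuroblastoma markers had 0.27 at the 99.8 percentile over 10 members, led by TAGLN and the smooth muscle actin ACTA2 at 0.89. Their median was 0.06 with Nondifferentiation as the reference, where siControl itself had -0.24. The hypoxia and glycolysis list had -0.19 at the 1.54 percentile over 13 members, with the mitochondrial kinase PDK1 at -1.02 and lactate dehydrogenase LDHA at -0.85. The noradrenergic list had -0.14 at the 1.48 percentile, with the noradrenaline transporter SLC6A2 at -0.54 and the transcription factor ISL1 at -0.46. The 47 ribosomal protein genes had -0.10 at the 0.16 percentile. With Nondifferentiation as the reference the noradrenergic median was -0.12 and the ribosomal median -0.03, both inside the middle 95% of random lists. The hypoxia and glycolysis median was then -0.46, where siControl itself had -0.25. The other preset lists with at least 5 measured members lay in that range against siControl. Against Nondifferentiation the synapse list had -0.59, cholesterol synthesis -0.46, the stress list -0.34 and mitotic genes 0.26, on the same side as siControl itself.

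Differentiation differed widely from Nondifferentiation. Of 9063 measured genes, 944 were higher and 991 were lower, and the retinoic acid response, HOX genes and some neuronal genes were on the higher side. Cell cycle genes, noradrenergic genes and glycolytic genes were on the lower side. CYP26B1 and CYP26A1, the cytochromes that degrade retinoic acid, stood at 16.22 and 14.38 in Differentiation and were both listed at 0 in Nondifferentiation. DHRS3, a reductase of retinaldehyde, stood at 11.98 against 1.77, and TGM2, a transglutaminase induced by retinoids, at 9.81 against 1.14. NTRK2, the receptor of brain-derived neurotrophic factor, stood at 8.84, and CRYM, a thyroid hormone-binding protein, at 11.47, both listed at 0 in Nondifferentiation. LINC01587 at 9.56, WDR86 at 9.25 and CD177, a surface protein of neutrophils, at 9.20 were also listed at 0 there. HLF, a transcription factor, stood at 8.38 against 0.26. No fold is given for these genes because the Nondifferentiation value came from 0 to about 3 reads.

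The lowest genes in Differentiation included the imprinted pair H19 and IGF2. H19, a noncoding RNA, stood at 9.60 in Nondifferentiation and was listed at 0 in Differentiation, and HOTS, which overlaps it, stood at -1.32 in Differentiation. IGF2, which encodes insulin-like growth factor 2, had a log2 fold of -4.97, and INS-IGF2, a readthrough transcript that shares its sequence, had -5.11. INSM2, a zinc finger transcription factor, had -6.14, the DNA helicase PIF1 -5.07, the transporter SLCO4A1 -4.29 and the semaphorin SEMA5B -4.01. FAM72A had -4.01 and the small noncoding RNA SNAR-C3 had -4.28, and both have near-identical copies that could share reads. Whether reads counted under SNAR-C3 came from the small RNA itself was not examined.

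Of 24 retinoic acid response genes 13 were measured in this pair, and of these 12 were higher in Differentiation and 0 were lower. Their median log2 fold was 5.20, above all 10000 random lists, and 3 members listed at 0 in Nondifferentiation lay above that median. RARB, a retinoic acid receptor chosen here after its value was seen, had 4.75, MEIS1 had 1.07 and STRA6, a retinol transporter, had 0.75. Of 26 HOX genes, 8 were measured in this pair and 5 in siControl against Nondifferentiation. Of the 8, 5 were higher, with HOXA3 at 3.90, HOXC5 at 1.94 and a median of 1.41 at the 99.8 percentile. A gene was measured by the larger of its 2 values, so genes low in Nondifferentiation entered only when high in Differentiation. This favours the higher side in lists with many such genes, and the counts are not shares of the whole lists. The growth media labels list 50 uM retinoic acid for both libraries of this pair. Of the 24 genes of the list 0 were counted as higher in Nondifferentiation than in siControl, whose label lists no retinoic acid, and 11 were in Differentiation. The 8 members measured in that pair had a median of -0.30 in siControl against Nondifferentiation, at the 0.19 percentile, with CRABP2 at -0.98 and RARA at -0.76, so part of the list lay on the higher side in Nondifferentiation.

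Neuronal genes were divided. Of 24 measured neuronal cytoskeleton and neurite genes, 5 were higher and 1 was lower, with a median log2 fold of 0.35 at the 97.9 percentile, and 0.27 at the 97.2 percentile after GC and length trends were removed. The adhesion molecule L1CAM and DCX had 1.93 each, while the neuronal tubulin TUBB3 had -1.11 and MARCKS -0.78. Of 26 synapse and granule genes, 14 were measured here and 9 in siControl against Nondifferentiation, so entry through a high Differentiation value limits this list too. Of the 14, 5 were higher and 1 was lower, and the median of 0.60 lay at the 90.9 percentile. SYT4 had 3.58 and the granule protein SCG2 had 2.64, while NPY had -3.09. Of 17 noradrenergic genes, 9 were lower and 0 higher, with a median of -1.50 below all 10000 random lists. DLK1, a Notch-like ligand of sympathoadrenal cells, had -3.59 and SLC6A2 had -3.47, while the lineage regulator PHOX2A had 0.57.

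Proliferation genes were lower nearly without exception. All 23 measured genes of G2 and mitosis were lower, with a median log2 fold of -2.58, and 19 of 20 S phase genes were lower, with a median of -2.12. Both medians lay below all 10000 random lists. CDC20, an activator of the anaphase-promoting complex, had -3.93, the spindle-linked HMMR had -3.80 and the proliferation marker MKI67 had -1.82. GINS2 and CDC45, parts of the replicative helicase, had -2.50 and -2.42, and the exception was the histone mRNA-binding SLBP at 0.11. Of 10 measured histone genes, 4 were lower and 1 was higher, with a median of -0.52 at the 5.27 percentile and folds from -1.80 to 2.08. Histone mRNA without a poly(A) tail is not read by this kit, so the list is no readout of S phase.

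Genes of glycolysis, cholesterol synthesis and the ribosome were also on the lower side in Differentiation. Of 12 hypoxia and glycolysis genes, 9 were lower and 0 higher, with a median of -1.42, LDHA at -3.17 and PDK1 at -2.81. Of 19 cholesterol synthesis genes, 6 were lower and 0 higher, with a median of -0.91. Both medians lay below all 10000 random lists. The 47 ribosomal protein genes had a median of -0.59 at the 0.11 percentile, and 4 were lower. The 19 nonsense-mediated decay targets had a median of -0.42 at the 2.3 percentile, the opposite side from siUPF1, and -0.27 at the 7.74 percentile after GC and length trends were removed, with ATF3 at -1.70 and the host gene SNHG1 at -1.67. The 6 Staufen-mediated decay targets had 0.19 at the 68.2 percentile, with GAP43 at 0.51 and CYR61 at -0.50. Decay factors had -0.05 at the 46.6 percentile, with the endonuclease SMG6 at 0.93 and the exon junction protein MAGOH at -1.20.

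Other preset lists lay inside the middle 95% of random lists in Differentiation. Of 21 interferon response genes, 4 were measured here and 2 in siControl against Nondifferentiation, so entry through a high Differentiation value limits this list too. Of the 4, 3 were higher, with BST2 at 1.95 and a median of 1.68 at the 97 percentile. The medians were 0.18 for immediate early genes, -0.11 for amino acid and endoplasmic reticulum stress, -0.15 for the p53 response, -0.09 for Notch and neural progenitor genes and -0.46 for mesenchymal markers. Among them the serine synthesis enzyme PSAT1 had -2.43, NOTCH2 had 2.09, the collagen COL3A1 had 2.45 and vimentin, VIM, had -1.25. With siControl as the reference of Differentiation the p53 median was 0.34, the stress median 0.14 and the mesenchymal median 0.20, so these 3 turned. With it the medians were 0.54 for immediate early genes, -0.27 for Notch genes, 1.09 for the synapse list, -0.50 for cholesterol synthesis, 0.39 for Staufen-mediated decay targets and -0.29 for decay factors. Schwann and glial markers did not reach the measured floor in any library. Of the blood markers only HBB, a haemoglobin chain, reached it, at 7.82 in Differentiation, with 7.76 in siSTAU1 and 5.92 in siControl. Of the preset symbols of the mitochondrial genome, 0 were among the deposited gene symbols, so that list could not be described.

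**Figure D2:**
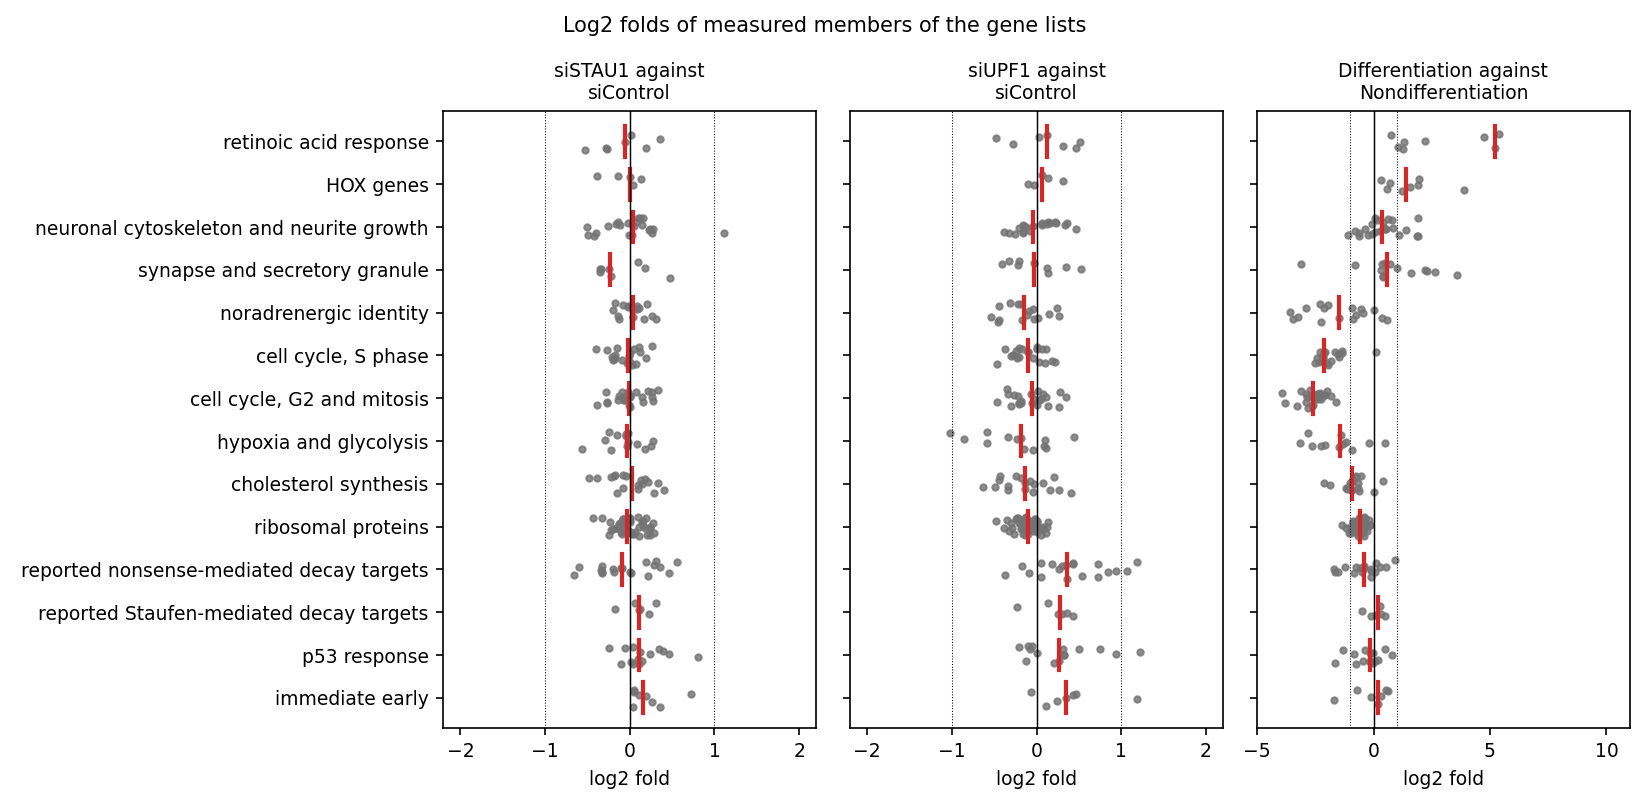
Log2 fold of each measured member (grey points) of 14 preset gene lists in the 3 comparisons, with the list median as a red bar, dotted lines at 2-fold, and a wider horizontal scale in the third panel. The 5 retinoic acid members with 0 to about 3 reads in Nondifferentiation are not drawn but enter the median. In Differentiation the retinoic acid median lay at 5.20 and the mitosis median at -2.58, while the nonsense-mediated decay targets had a median of 0.36 in siUPF1.

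The 2 reference libraries, siControl and Nondifferentiation, gave a measure of how far libraries without knockdown or differentiation lay apart, although they also differed in transfection and in the labelled medium. Of 8546 measured genes, 19 were higher and 49 were lower in siControl. PTGS1, a cyclooxygenase, had a log2 fold of -4.77, H19 -2.87, IGF2 -2.35 and TH, the first enzyme of catecholamine synthesis, -2.13. VGF had -2.10, CDKN1A -1.83 and EGR1 -1.72, while IGFBP3 had 2.30, IGFBP5 1.43 and PLXNA4, a semaphorin receptor, 1.35. Mitotic genes had a median of 0.33, above all 10000 random lists. Lower medians stood at -0.50 for immediate early genes, -0.41 for the synapse list, -0.38 for the p53 response, -0.36 for cholesterol synthesis, -0.30 for the retinoic acid response, -0.25 for hypoxia and glycolysis, -0.24 for mesenchymal markers and -0.28 for both the stress list and the Staufen-mediated decay targets. The SD of log2 folds over genes was 0.314 here, against 0.246 for siSTAU1, 0.289 for siUPF1 and 1.05 for Differentiation.

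Of the 8237 genes measured in all 3 comparisons, 1 was higher in all, IGFBP3. Its log2 folds were 1.07 in siSTAU1, 1.41 in siUPF1 and 1.40 in Differentiation. Among these 8237 genes 2 were higher in siSTAU1, 20 in siUPF1 and 570 in Differentiation, fewer than in the full lists because a gene had to be measured in all 3. Independent lists of these sizes would share 0.000336 genes, but this is no valid value for unchanged genes. A gene was measured by the larger of its values, so the change itself let some genes in. IGFBP3 lay below the floor in Nondifferentiation and was measured in that pair only through Differentiation. The same limit applies to the value for independent lists at 1.5-fold. Simulated unchanged libraries had 0 calls in either knockdown, which fixes their overlap. IGFBP3 stood at 9.61 in siControl, 7.31 in Nondifferentiation and 8.71 in Differentiation, so against siControl it was lower in Differentiation and 0 genes were higher in all 3. At 1.5-fold 6 genes were higher in all 3, against 0.271 for independent lists: IGFBP3, the adaptor KAZN, the ubiquitin ligase subunit RBCK1, CARF, the kinase MOK and the transcription factor PAX5. The next by their smallest fold were HAGLR, a noncoding RNA of the HOXD cluster, at 0.58, the axon guidance ligand SLIT2 at 0.56, the phosphodiesterase PDE8B at 0.55 and PQLC3 at 0.55. No gene (0 of 8237) was lower in all 3 at 2-fold, and 4 were at 1.5-fold: IGF2, INS-IGF2, GCDH, an enzyme of lysine breakdown, and CCDC85B. Part of any overlap of the knockdown libraries may come from their shared control.

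Pairs of comparisons overlapped unevenly. Between siUPF1 and Differentiation 6 genes were higher in both, PAX6, GABARAPL1, ASL, IGFBP3, CARF and PLCE1, against 1.87 for independent lists of 26 and 601 among the 8340 genes measured in both. In Nondifferentiation PAX6 stood at 7.47 and IGFBP3 at 7.31, below the floor, and ASL at 9.19, above it. PAX6 and IGFBP3 were thus measured in that pair only through Differentiation, so 1.87 is no valid value for unchanged genes. This limit applies to every value for independent lists in this paragraph. At 1.5-fold 98 were higher in both, against 42.5, and 57 were lower in both, against 27.0. Between siSTAU1 and Differentiation 4 were higher in both, SNORA12, IGFBP3, DCX and PRICKLE1, against 0.350 for lists of 5 and 581 among 8304 genes. In Nondifferentiation IGFBP3, DCX and PRICKLE1 stood at 7.31, 7.51 and 7.67, below the floor, and SNORA12 at 8.15, above it. RTEL1 and TUBA1C lay below the floor in both libraries of that pair and were left out, so the share of siSTAU1 genes in the overlap is inflated. At 1.5-fold 20 were higher in both, against 13.1, and 17 were lower in both, against 23.4. Across genes, which are not independent replicates, the Pearson correlation of log2 folds was 0.253 for siUPF1 and Differentiation and 0.0271 for siSTAU1 and Differentiation. The Spearman values were 0.264 and 0.0203, and neither pair shared a library. For siSTAU1 and siUPF1 the correlation was 0.415, below the 0.522 that simulated unchanged libraries gave through the shared siControl. Sharing a control sets such a correlation largely by itself, whatever the size of the error. The covariance was 0.0271 against a simulated 0.00391, but the simulation holds counting error only, so the part from the shared culture is not in it. With Nondifferentiation as the reference for siUPF1 alone this correlation was -0.0544, and for siSTAU1 alone -0.114.

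**Figure D3:**
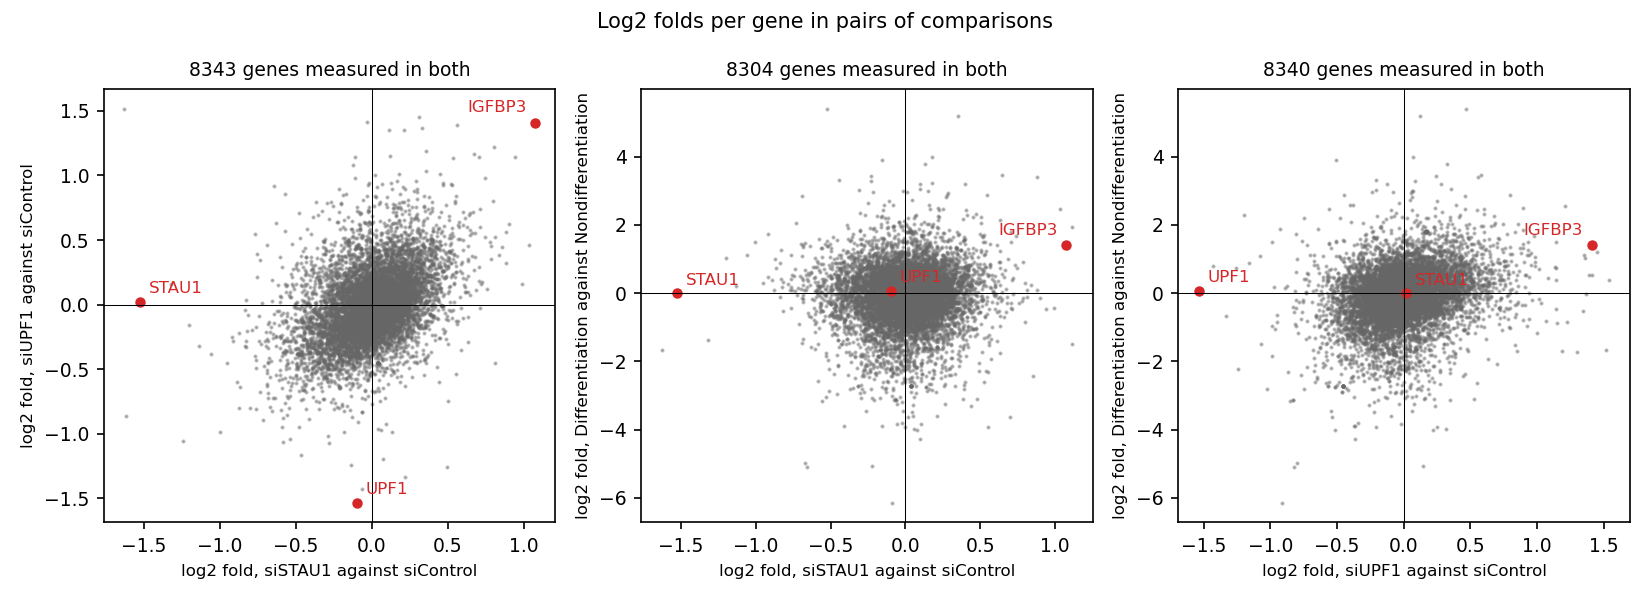
Log2 folds of single genes (grey points) in pairs of comparisons, with IGFBP3, STAU1 and UPF1 in red. The siSTAU1 and siUPF1 folds in the left panel share the siControl library and had a correlation of 0.415. A simulation with counting error only gave 0.522 through the shared library, a value set largely by the sharing itself. The middle pair had 0.0271, and siUPF1 and Differentiation in the right panel had 0.253.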

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

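The pseudocount of 10, siControl as the reference of Differentiation, Nondifferentiation as the reference for knockdown gene lists and the removal of GC and length trends were chosen after the data were seen. Counts are given as higher and lower genes, in the order siSTAU1, siUPF1, Differentiation and siControl against Nondifferentiation. The reported counts were 8 and 9, 34 and 12, 944 and 991, and 19 and 49. Without a filter they were 1353 and 1298, 1401 and 1297, 2828 and 3444, and 1260 and 1428, since genes of a few reads enter. With the upper quartile filter, under which fewer genes were tested, they were 1 and 2, 10 and 2, 487 and 513, and 4 and 18. At 1.5-fold they were 86 and 109, 254 and 132, 1977 and 1970, and 193 and 274. At 3-fold they were 1 and 2, 2 and 0, 370 and 426, and 1 and 12. With Nondifferentiation as the reference, siSTAU1 had 24 and 54, and siUPF1 had 46 and 71, so its balance turned round. With a pseudocount of 10 the genes higher in siControl than in Nondifferentiation were 12. siControl itself had 19 higher and 49 lower against Nondifferentiation, a gap that is by construction part of each knockdown fold with that reference. The cause was not tested for the pseudocount.

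Genes higher in all 3 comparisons numbered 163 without a filter, 0 with the upper quartile filter, 6 at 1.5-fold, 0 at 3-fold and 0 with siControl as the reference of Differentiation. Genes lower in all 3 numbered 189 without a filter and 4 at 1.5-fold. The correlation of siSTAU1 and siUPF1 was -0.0544 with Nondifferentiation as the reference for siUPF1 and -0.114 with it for siSTAU1, which by construction removes the shared library. The correlation of siUPF1 and Differentiation was 0.0861 without a filter, where genes of a few reads enter. In siUPF1 against Nondifferentiation the list medians were -0.0365 for Staufen-mediated decay targets, -0.0653 for immediate early genes and -0.21 for the p53 response. siControl itself had -0.28, -0.50 and -0.38 with that reference. By construction this gap between the reference libraries is part of each siUPF1 fold there, so the turns came from Nondifferentiation as the reference. With that reference 23 other list medians in the knockdowns moved by over 0.1 and 12 did not. With siControl as the reference 15 list medians of Differentiation moved by as much and 5 did not. Over the 3 comparisons 15 moved and 38 did not with the upper quartile filter, 13 moved and 45 did not without a filter, and 12 moved and 46 did not after the removal of GC and length trends. Subtracting the median fold kept all results within these bounds. Repeated quantile normalization moved no gene above the floor by more than 0.00435 log2, so it is no check. No paired analysis was possible because each group had 1 library, and leaving out a library was not possible for the same reason. Depth limits the low end, where genes below the floor rest on fewer than about 181 reads in siControl.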

Other observations

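Of the tests in this part, those on the siControl library, on nonsense-mediated decay in Differentiation, on the spread of the reference libraries, on luminal breast and hepatocyte transcripts and on retinoic acid in Nondifferentiation were chosen after the result was seen.

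Families of gene symbols were compared in Differentiation after the preset lists. All 18 measured SNAR genes, small noncoding RNAs of primates, were lower, with a median log2 fold of -2.74. All 13 measured PCDHA and 12 PCDHGA protocadherin genes, which encode neuronal adhesion molecules, were higher, with medians of 1.80 and 1.15. SNAR folds ran from -4.28 to -2.74, with several symbols at identical values, and the protocadherin folds lay close together within each family. SNAR copies are near-identical and each protocadherin cluster shares its 3' exons, so these are not independent measurements. The kit reads polyadenylated RNA, and whether reads counted under SNAR symbols came from the small RNAs themselves was not examined. Of mitochondrial ribosomal protein genes 12 of 43 MRPL and 4 of 25 MRPS genes were lower, with medians of -0.72 and -0.61. Of the NUP genes of the nuclear pore 7 of 18 were lower, with a median of -0.84, and of the SNHG genes, hosts of small nucleolar RNAs, 6 of 14, with -0.99. The 255 measured ZNF zinc finger genes had 0.31, with 21 higher and 7 lower. These were 8 of 85 families examined.

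A list of autophagy genes without the ATG symbols was on the higher side in Differentiation, whereas the 15 measured ATG genes had a median of 0.19 at the 82.8 percentile and 0 were higher. All 18 measured members of the list had positive log2 folds, 5 of them were at least 2-fold higher, and the median of 0.61 lay at the 99.9 percentile of random lists. The protease CTSB had 3.21, the autophagy receptor OPTN 1.72, the lysosomal regulator TFEB 1.31 and MAP1LC3A, which coats autophagosomes, 1.20. The list had been written to ask whether autophagy genes as a class might be higher in both knockdowns, after the ATG symbols had stood out there. They were not: the lower of its 2 percentiles was 27.7, in siSTAU1.

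The low values of H19 and IGF2 led to the hypothesis that imprinted genes as a class might be lower in Differentiation. A list of imprinted genes not yet looked at, 14 of them measured, had a median log2 fold of 0.16 at the 81.9 percentile, which argues against it. PEG10 had -2.46 and BLCAP 1.16.

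The labelled retinoic acid in Nondifferentiation raised the hypothesis that those cells could have responded as Differentiation cells did. Of the 24 genes of the retinoic acid list, 0 were counted as higher in Nondifferentiation than in siControl and 11 were in Differentiation, which argues against a response of that size. CYP26B1 stood at 16.22 in Differentiation and was listed at 0 in Nondifferentiation. A weak response stays open, because the list had a median of -0.30 in siControl against Nondifferentiation, at the 0.19 percentile, with CRABP2 at -0.98. A label that lists the medium of the experiment rather than of the library stays open and untested.

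The folds of siUPF1 and Differentiation were correlated across genes, at 0.253, although they share no library. Shared trends with GC content and length of the longest transcript were argued against as the source of the correlation. It was 0.246 after those trends were removed and 0.245 before in the same genes. The folds went with GC at 0.27 in siUPF1 and 0.11 in Differentiation, and with length at -0.12 and 0.19. These could offset each other, so the share of GC by itself was not tested. The kit reads 3' ends, so bias of the sequenced fragments was not tested either and stays open. An odd siControl library was argued against by the correlation of 0.0271 between siSTAU1 and Differentiation, which uses the same siControl. Less nonsense-mediated decay in Differentiation stays open: its targets had a median of -0.42 there at the 2.3 percentile, but -0.27 at the 7.74 percentile after those trends were removed. An effect of UPF1 on genes of differentiation through another route, or an odd siUPF1 library, may remain, and neither was tested.

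The knockdown libraries differed little from siControl. Simulated counting error gave an SD of up to 0.0900, but it leaves out the spread between cultures, so with 1 library per group it decides nothing about the observed 0.246 and 0.289. Differences of the size seen between the reference libraries could account for the whole spread, since their SD was 0.314. That pair also differed in transfection and in the labelled medium, so it is no replicate spread. Effects of the siRNAs on single genes stay open, and only STAU1 and UPF1 themselves were predicted by the labels.

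Transcripts of other cell types stood out in the knockdown libraries and, for epithelial ones at lower values, in Differentiation. RNA or reads of luminal breast epithelial cells are a candidate source in siSTAU1: of 35 such markers without DSCAM-AS1, 26 were highest in siSTAU1 among the 4 libraries other than Differentiation. The preset epithelial list held 9 of the 35, and siControl expressed 2 above the floor. The 26 outside the epithelial list had a median above that of all random lists, at the 100 percentile, with TFF1 at 5.50 and TFAP2C at 4.43 in siSTAU1 and both listed at 0 in siControl. Some of these transcripts were also in siUPF1, with ESR1 at 4.74, KRT18 at 4.74 and KRT8 at 4.23, while the median of the 26 lay at the 48.6 percentile there. Differentiation, left out of that ranking, held KRT8 at 4.58, KRT18 at 3.54, ESR1 at 3.41 and TFF1 at 3.04. Against a full luminal profile, EPCAM stood at 2.26 and AGR2 at 2.26 in siSTAU1, and FOXA1 at 4.74 there against 4.98 in siControl. Hepatocytes as the source of ALB in siUPF1 were argued against, since the largest excess of any of 24 other hepatocyte markers, APOB, was 1.94% of that of ALB, and TTR, SERPINA1 and FGA were listed at 0. Activation of these genes by loss of STAU1 or UPF1 was not tested.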
